A study of Caenorhabditis elegans with 2 samples.

How the data were processed

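Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used by the authors to map where LET-607 sits on the genome of Caenorhabditis elegans. LET-607 is a basic leucine zipper transcription factor related to the mammalian CREB3 family. Per the labels, the worms carried a let-607 mutation and an integrated fosmid with a GFP- and FLAG-tagged copy of the gene together with the unc-119 marker. They were grown from starved first-stage larvae and collected as mixed-sex young adults at 49.5 hours. Chromatin was sonicated to 200 to 800 bp and precipitated with an antibody against GFP, per the labels' protocols. The series holds 1 group of 2 biological replicates, so no comparison between conditions exists in the design and the p-values below are over regions or genes, not over cultures of worms.

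The deposited files are lists of regions with a summit each. The text deposited with them says that each list was called from the replicate alignments and a control alignment on the ce11 assembly, and that the thresholded list was derived from both replicate lists and a pooled list by the irreproducible discovery rate (IDR). The deposited signal value of each region is the authors' peak caller's own value, and its formula is not given in the sources used here. It was used to rank regions within a list, to compare bound genes within the thresholded list, and to correlate the replicates over matched regions; a fold of it is a ratio of this score, not of bound protein. The deposited −log10 q-value is also the authors' own and reaches a ceiling shared by many regions. The aligner, the peak caller and their versions are not given in the sources used here. The files give no read counts, so the depth of each library is unknown, and the control library was not analysed here.

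Positions are 1-based on ce11. Genes, transcript starts and tRNA genes came from Ensembl release 115 for the matching assembly, and sequence came from the reference FASTA. A protein-coding gene was called bound when a thresholded summit lay from 1000 bp upstream to 200 bp downstream of any of its annotated starts. A summit between divergent genes therefore counts for both. The background was the 7766 protein-coding genes with any pooled or thresholded region in that window. The other 12207 of 19973 protein-coding genes had no such region and stayed out of the tests. Annotated starts of worm genes are often trans-splice sites, and operons were not treated separately.

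The tests, the 27 gene lists, the 9 motifs and the rule for named genes were fixed before the data were examined, except those named as chosen later in the closing part. Gene lists were tested with a two-sided Fisher's exact test against the background, adjusted by the Benjamini-Hochberg method over the lists. Listed names without a match among annotated protein-coding genes were left out. The union of the secretory lists was tested once more on its own. Promoter shares were compared with 1000 uniform shuffles of the summits within chromosomes. Signal at secretory genes was compared with other bound genes by a two-sided permutation test of 100000 resamples of the difference in median log2 signal. Motifs were counted on both strands in the 101 bp centred on each summit and compared with the 101 bp lying 300 bp to the left by a two-sided exact McNemar test. All 8-mers found in at least 10 summit windows were compared with the mean of both flanks by a one-sided Fisher's exact test, which ignored the pairing. This filter looked at summits alone, so it favours 8-mers that are frequent there. Intervals on shares are 95% Wilson intervals and cover counting error only.

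Replicates were compared by the share of the 1488 strongest regions of replicate 1 whose summit fell inside one of the 1488 strongest of replicate 2, with 100 shuffles for the chance level. Named genes were let-607 and unc-119, the nearest genes of the 20 strongest regions, and up to 4 strongest bound members of each secretory list and of each other list past the adjusted threshold of 0.05. Up to 2 unbound members of the list of unfolded protein response regulators were added. The 5 8-mers with the smallest p were also named. Alternatives changed the threshold (the 744 strongest regions), the window, the background, the flank, the summit window, the matching rule, and left out each replicate by using the 1488 strongest regions of the other one alone. In the setting with the nearest start alone, each summit counted only for the closest start among those whose promoter window held it.

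The statistics were tested on simulated data. In a simulated list of gene calls over 7766 genes, a planted bound share of 50% was recovered as 48.3%, and 0 of 200 unrelated lists passed. A motif planted in 10% of 1488 simulated windows was found in 10.1% of them and ranked 1 among the 8-mers. With that single planted sequence 11 8-mers passed, and all 11 shared at least 6 bases in a row with it, so a count of 8-mers past the threshold is not a count of separate elements. Matching recovered 60.1% of regions where 59.9% had been kept in place. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.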

Results

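The data are region lists from 2 biological replicates of LET-607-GFP ChIP-seq in young adult worms. Replicate 1 had 30000 candidate regions and replicate 2 had 26493, with median widths of 404 and 424 bp. The pooled list held 30000 regions, and the thresholded list held 1488, which were the 1488 pooled regions with the highest signal. Their signal ranged from 111 to 6859 with a median of 158. Because 36 regions overlapped the one before, they formed 1452 separate stretches. Read depth is unknown.

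The strongest regions lay at genes of the protein translocation and folding machinery of the endoplasmic reticulum (ER). The top region, at X 767940 to 768525, was intergenic between trap-2, a subunit of the translocon-associated protein complex, and ile-2, a lectin-type cargo receptor, with a signal of 6859. The region at IV 2388827 to 2389437 stood between trap-3 and sec-61.B, a subunit of the SEC61 translocation channel, with a signal of 6299. They were followed by serp-1.1, which is not in the fixed lists, at 5430.1, sec-61.G at 5225, sec-61.A with the divergent ribosomal gene rps-18 at 4424, and hsp-3, an ER Hsp70 chaperone of the BiP type, at 4418. Of the 20 strongest regions, 12 had a gene of the fixed secretory lists in the promoter window.

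The rest of the top 20 held further ER genes and several others. The signal was 3440.0 at trap-1, 3391 at enpl-1, an ER Hsp90 chaperone, 2414 at the protein disulfide isomerase gene pdi-1, 1595 at crt-1, which encodes calreticulin, and 1509.7 at trap-4. The gene of the unfolded protein response regulator xbp-1 had a region at III 4193519 to 4194037 with a signal of 2808. The region between pdi-3 and ubql-1, the ubiquilin gene, reached 2154, and that at calu-1, the calumenin gene, reached 2223. Outside the secretory lists were serp-1.1, calu-1, C48B6.10 at 2796, F10G7.9 with tsn-1 at 2124, srh-70 with ceh-99 at 1609 and iff-2 at 1546. The regions nearest to F17C11.22 (1938) and ppfr-1 (1383) lay in introns.

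**Figure D1:**
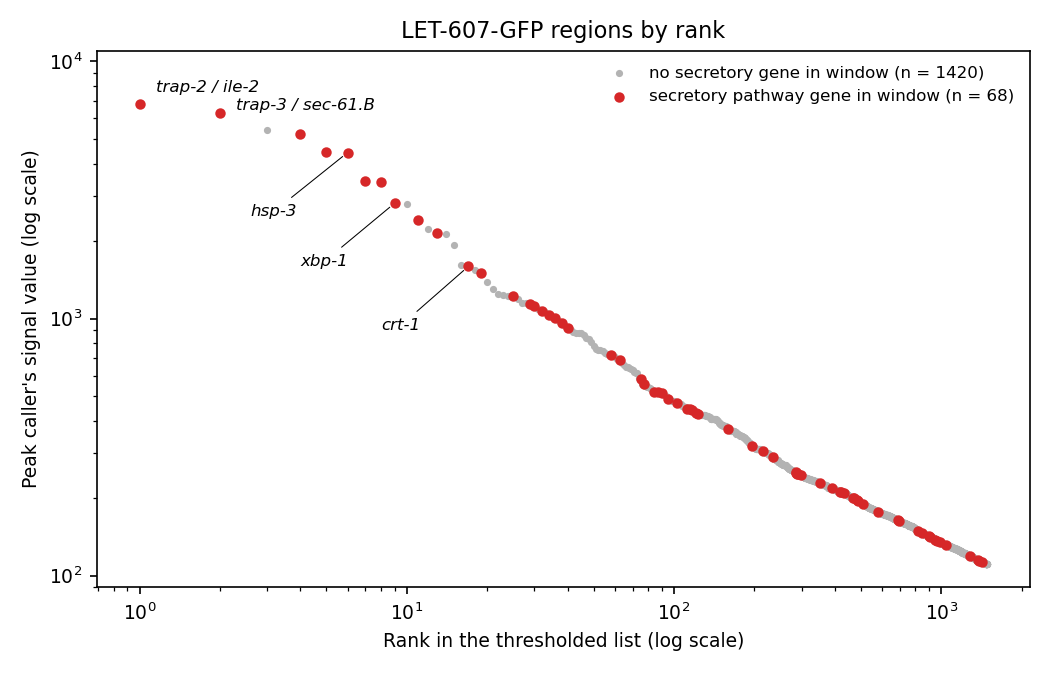
Signal value of the peak caller (log scale) against rank (log scale) for the 1488 thresholded regions, with regions that have a secretory pathway gene in the promoter window in red. The 68 red points include 12 of the 20 strongest regions.

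The 20 strongest regions ranked high in both replicates, no lower than 20 in replicate 1 and 22 in replicate 2. Their choice by the pooled signal of the same replicates favours this by construction. The trap-2 region had a signal of 3106 in replicate 1 and 3782 in replicate 2, and ranked 1 in both. The xbp-1 region ranked 10 and 9. Of the 1488 thresholded regions, 1479 were found among the candidates of both replicates, which their derivation from both replicate lists favours by construction. When the 1488 strongest regions of each replicate were set against each other, 981 were shared, or 65.9% (63.5 to 68.3), against a chance level of 0.606% that never passed 1.08% in 100 shuffles. Across the 1479 regions the Spearman correlation of signal was 0.588 and the Pearson correlation of log2 signal was 0.811, each with a permutation p of 1e-05, the smallest that 100000 permutations can give. These regions were selected with the same 2 replicates, so the correlations describe the selected regions only, and regions are not independent replicates. With 2976 regions per replicate the shared part was 56.7%.

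Across the fixed lists, genes of the secretory pathway were bound far more often than the background. Of 120 secretory genes with a candidate region, 66 were bound (55.0%), against 958 of 7766 background genes, with an odds ratio of 9.25 (95% interval 6.31 to 13.6, Fisher's exact p = 1.04e-29). Genes that share a region count separately here. With the nearest start alone 51 of 120 were bound (42.5%, odds ratio 7.20, Fisher's exact p = 3.07e-21). Of all 157 annotated secretory genes, with or without a candidate region, 42.0% were bound, against 4.80% of all protein-coding genes. Of 27 lists, 9 were above and 2 were below the background at an adjusted p under 0.05. The median signal of bound secretory genes was 445, against 169 for the other 892 bound genes. The log2 difference in medians was 1.40 (2.63-fold, permutation p = 1e-05, the smallest possible). Genes that share a region carry the same signal in this test, so they are not independent.

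ER targeting and translocation had 12 of 13 genes bound (92.3%, Fisher's exact adjusted p = 3.64e-09), with a median signal of 3415. The 24 names of this list gave 16 annotated genes, of which 3 had no candidate region, so 75.0% of the annotated genes were bound. Several of these genes share a region with a divergent neighbour, and with the nearest start alone 7 of 13 were bound (53.8%, exact adjusted p = 0.000586). The gene sec-61.A was lost there although its own start was the nearest. Its summit lay 254 bp downstream of that start, beyond the 200 bp limit of the window. ER folding had 13 of 22, led by hsp-3, enpl-1, pdi-1 and pdi-3 (exact adjusted p = 2.17e-06). In the fixed list of unfolded protein response regulators, 6 of 9 genes were bound (exact adjusted p = 0.000808). They were xbp-1, let-607 itself at 690.3, the ER stress sensors pek-1 at 212 and ire-1 at 211, and crh-2 and atf-6, which the naming rule did not pick. The list members atf-4 and crh-1 had candidate regions that stayed below the threshold.

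Vesicle coats and receptors between the ER and the Golgi followed. COPII, the coat that buds from the ER, had 6 of 8 genes bound (exact adjusted p = 0.000421), with sec-24.1 at 1225, sar-1 at 1071, sec-23 at 919 and tfg-1 at 427. The sec-23 region lies nearer to another gene's start, and with the nearest start alone sec-23 ranked 968 instead of 40. COPI, the coat of return transport, had 5 of 8 (exact adjusted p = 0.00344), with copa-1 at 442, copb-2 at 372, copd-1 at 289 and copg-1 at 190.1. Cargo receptors had 7 of 12 (exact adjusted p = 0.000808), with erd-2.1, a receptor for ER retention signals, at 724, ile-1 at 511 and tmed-3 at 488. The fixed list for ER-Golgi tethering and fusion had 10 of 25 (exact adjusted p = 0.0015). Its strongest bound members were the syntaxin gene syx-5 at 1135, nbet-1 at 518, rab-11.1 at 446 and rab-1 at 251. The COPI call ended with the 500 to 100 bp window (3.62-fold, exact adjusted p = 0.0930). The tethering call ended with the nearest start alone (2.44-fold, exact adjusted p = 0.0691), where syx-5, rab-11.1 and rab-1 were no longer bound.

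N-glycosylation (4 of 15, exact adjusted p = 0.175) and ER-associated degradation (3 of 8, exact adjusted p = 0.125) did not pass. Their bound members were dad-1 (516), ribo-1 (249), ostb-1 (209.9) and dpm-3 (164), and cdc-48.1 (1002), ubc-6 (196) and cup-2 (177). On replicate 2 alone ER-associated degradation passed, with 4.03-fold and an exact adjusted p of 0.0245.

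**Figure D2:**
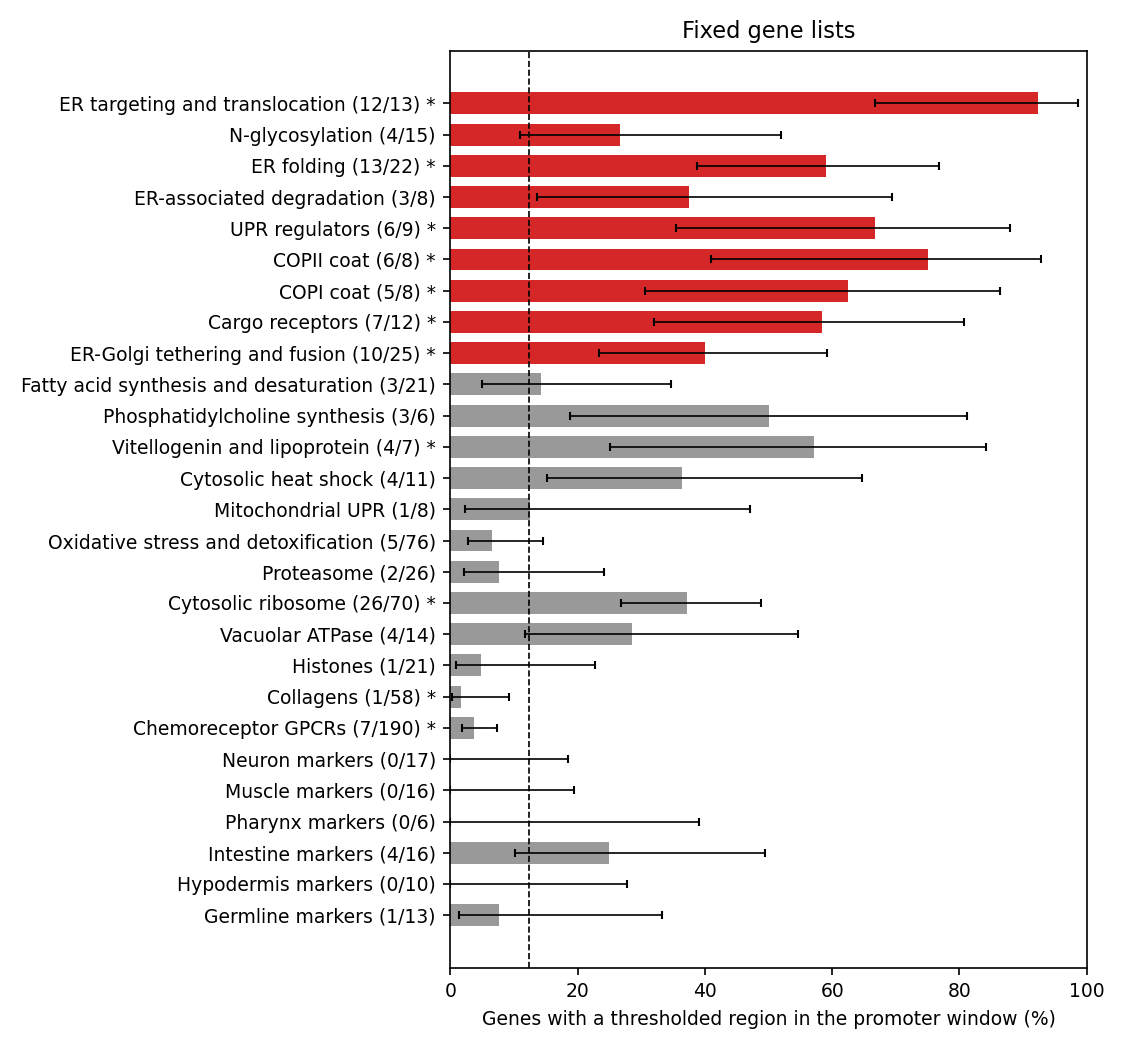
Percent of genes with a thresholded region in the promoter window for each fixed list, secretory lists in red, with 95% Wilson intervals, bound and background genes in brackets, and an asterisk for an adjusted p under 0.05. The dashed line is the background share, 958 of 7766 genes, and ER targeting and translocation reached 92.3%.

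Outside the secretory pathway, cytosolic ribosomal protein genes were bound at 26 of 70 (37.1%, 3.01-fold, exact adjusted p = 1.17e-06), with a median signal of 259. With the nearest start alone the count was 16 of 70 (2.33-fold, exact adjusted p = 0.00384). Besides rps-18, whose region is shared with sec-61.A, the strongest were rpl-1 at 1249.7, rpl-3 at 709 and rpl-20 at 543. Vitellogenin and lipoprotein genes, which encode yolk proteins and related carriers, had 4 of 7 bound: vit-6 (213), vit-2 (209), vit-3 (199.99) and vit-1 (131), with an exact adjusted p of 0.0160. That call ended on replicate 1 alone (3.54-fold, exact adjusted p = 0.0956), and vit-3 has near-identical copies, so its reads are uncertain.

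Collagens had 1 of 58 bound, col-38 at 195 (exact adjusted p = 0.0196), and chemoreceptors had 7 of 190 (exact adjusted p = 0.000317), among them srh-70, srh-16 at 248, sre-23 at 240.5 and srr-10 at 235. The collagen call ended on replicate 1 alone (0.427-fold, exact adjusted p = 0.258) and on replicate 2 alone (0.278-fold, exact adjusted p = 0.0877), and both calls ended with the 500 to 100 bp window.

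Lists of other processes and tissues did not pass. Cytosolic heat shock genes were bound at 4 of 11 (exact adjusted p = 0.0773), but passed on replicate 2 alone (4.40-fold, exact adjusted p = 0.00256) and on replicate 1 alone (3.76-fold, exact adjusted p = 0.0190). Phosphatidylcholine synthesis had 3 of 6 (exact adjusted p = 0.0631), vacuolar ATPase 4 of 14, fatty acid synthesis and desaturation 3 of 21, the mitochondrial unfolded protein response 1 of 8, oxidative stress and detoxification 5 of 76, the proteasome 2 of 26 and histones 1 of 21. Among tissue markers, intestine had 4 of 16 (exact adjusted p = 0.199), germline 1 of 13, neuron 0 of 17, muscle 0 of 16, pharynx 0 of 6 and hypodermis 0 of 10. With so few genes, the upper 95% limits for the last 4 were 18.4%, 19.4%, 39.0% and 27.8%.

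Regions lay at promoters more often than shuffled ones. Of the 1488 summits, 795 (53.4%) fell in the promoter window of a protein-coding gene, against 25.5% after shuffling (2.09-fold, permutation p = 0.000999, the smallest that 1000 shuffles can give). Pooled candidates outside the thresholded list had 30.2% there (1.77-fold, Fisher's exact p = 3.59e-73). By annotation, 923 of the 1488 summits were intergenic, as were 37.2% of random positions. Introns held 25.1% of summits (33.9% at random), coding exons 6.65% (23.4%) and 3' UTRs 2.02% (3.71%), and 61 summits were in 5' UTRs, against 1.70% at random.

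Chromosome X carried trap-2, serp-1.1, hsp-3 and calu-1 among the strongest regions and 359 of 1488 regions in all. The pooled candidates outside the thresholded list had 18.5% on X, an odds ratio of 1.40 (Fisher's exact p = 1.50e-07). Without regions within 500 bp of a tRNA gene, a setting chosen after the data were seen, it was 1.16 (exact p = 0.0294). X had 20.3 regions per Mb, and the autosomes ranged from 9.75 on V to 17.8 on III.

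Sequences with an ACGT core were found at summits more often than in the left flank. TGACGTGG, the type of element bound by unfolded protein response regulators, was in 28 summit windows and 6 flanks (4.67-fold, exact McNemar adjusted p = 0.000107), and on replicate 2 alone the ratio was 3.00 (exact adjusted p = 0.00377). TGACGTGK was in 52 and 10 (5.20-fold, exact adjusted p = 3.53e-08), and the E-box CACGTG in 116 and 25 (4.64-fold, exact adjusted p = 9.95e-16). The shorter TGACG was in 324 and 155 (exact adjusted p = 2.26e-16) and ACGT in 508 and 280 (exact adjusted p = 1.36e-20). TGATAA (230 and 158, exact adjusted p = 0.000192) and GAGAGAGA (50 and 19, 2.63-fold, exact adjusted p = 0.000196; 4.38-fold on replicate 2 alone) also passed. TGACGTCA (11 and 9, exact adjusted p = 0.824) and WWTRTCAT (70 and 89, exact adjusted p = 0.164) did not. Against candidates matched on GC content the TGACGTGG call ended (1.65-fold, Fisher's exact adjusted p = 0.132). TGACGTGK and CACGTG fell to 2.36-fold and 2.58-fold there, TGACG and ACGT to 1.40-fold and 1.41-fold, and all of these still passed. TGATAA rose from 1.46-fold to 2.21-fold, with the smallest Fisher's exact adjusted p of the 9 motifs (1.96e-12). The ratio of WWTRTCAT changed direction, from 0.787 to 1.84, and passed (Fisher's exact adjusted p = 0.00287).

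The longer elements were found near the summits of several named genes. These are examples, and the elements are not shown to be the bound sites. Over the 1488 regions TGACGTCA was in 11 summit windows and 9 flanks, and TGACGTGG did not pass against GC-matched candidates. In the intergenic region of xbp-1, TGACGTCA stood at III 4193736 to 4193743 on the plus strand, 28 bp from the summit, in the sequence CTCCCTCTTGACGTCATTTCCCAT. In that of crt-1, TGACGTGG stood at V 6100787 to 6100794 on the minus strand, in CCAGTCGCTGACGTGGACCAATAG, and in that of erd-2.1 at X 10158880 to 10158887 on the minus strand, 2 bp from the summit, in ACACTGTGTGACGTGGACGAATAG. The elements of ostb-1 (II 7864436 to 7864443, TTCGAATTTGACGTGGCACAATCG) and rab-1 (V 1264488 to 1264495, GGGAGAAATGACGTGGCGAGGCAG) were on the plus strand. The strongest region, at trap-2, had TGACG but no ACGT in the window centred on its summit at 768239, which read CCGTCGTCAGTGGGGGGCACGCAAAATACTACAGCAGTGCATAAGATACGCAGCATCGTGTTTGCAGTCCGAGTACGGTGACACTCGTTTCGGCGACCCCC on the plus strand.

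Of 2891 8-mers tested, 511 were more frequent at summits at an adjusted p under 0.05, and overlapping 8-mers count separately. The tested 8-mers were chosen by their count at summits, which favours such calls by construction. The 8-mers were not set against GC-matched candidates. The 5 with the smallest p overlap one another and share ACGC. AGACGCAG was in 83 summit windows against a flank mean of 8 (one-sided Fisher's exact adjusted p = 4.18e-14), GACGCAGA in 74 against 6.5, GAGACGCA in 69 against 6, ACGCAGAC in 47 against 2.5 and AGAGACGC in 55 against 6.5. The summit window of hsp-3, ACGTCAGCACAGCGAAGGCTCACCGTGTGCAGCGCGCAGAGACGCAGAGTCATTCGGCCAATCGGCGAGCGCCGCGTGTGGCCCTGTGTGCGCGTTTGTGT, holds AGACGCAG.

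**Figure D3:**
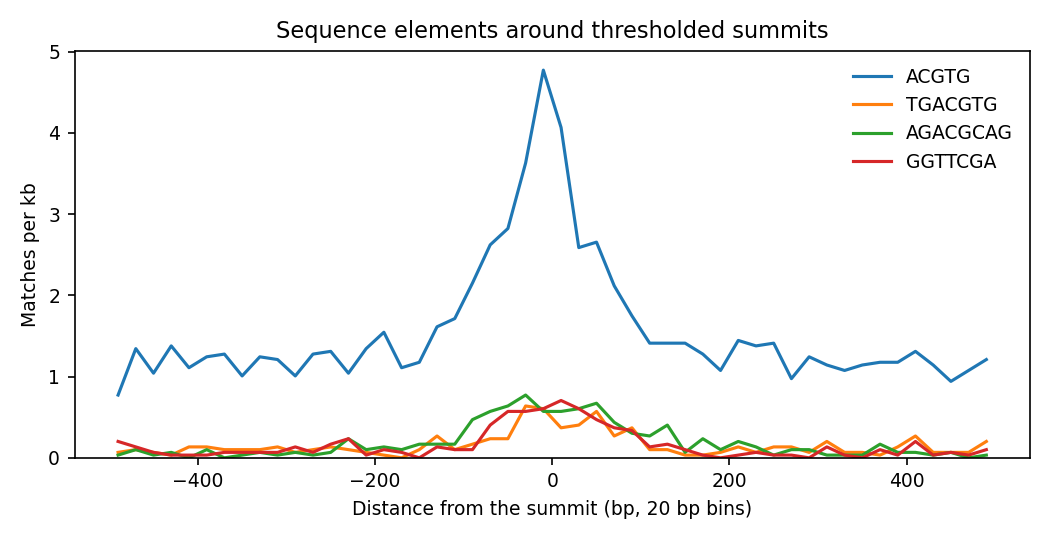
Matches per kb of 4 sequence elements in 20 bp bins against distance from the summit in bp, over the 1488 thresholded regions. Each line is 1 element, and all 4 are most frequent within 100 bp of the summit.

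The regions at let-607 and unc-119, the genes named for the transgene, differed from each other. At let-607, whose fosmid copy the worms carried, the strongest region was in the 5' UTR at I 6579909 to 6580141, with a signal of 690.3 and rank 63. It lay in a run of 17 thresholded regions from 6554659 to 6589225, a span of 34567 bp that also held the regions of dad-1 and tmed-3. Without the run, a setting chosen after the data were seen, let-607, dad-1 and tmed-3 were no longer bound. This follows by construction, since their regions lay in the run. The strongest candidate over unc-119 ranked 2982 in the pooled list with a signal of 81.3 and was below the threshold. The labels do not say which unc-119 sequence the transgene holds, so the unc-119 gene on ce11 need not be part of it.

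**Figure D4:**
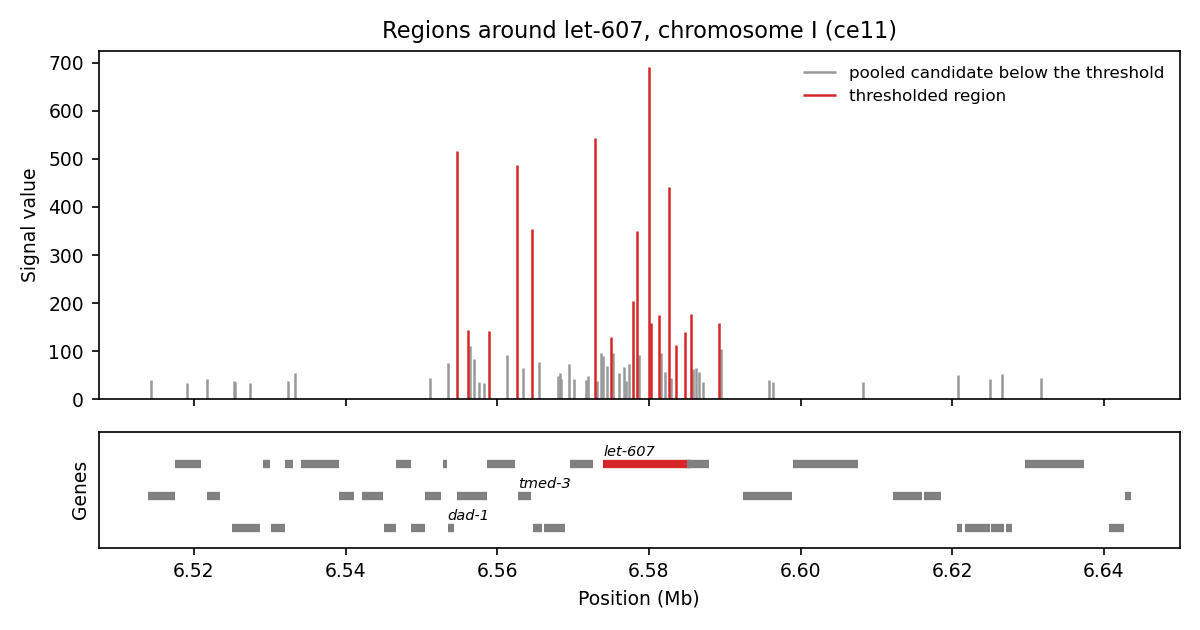
Signal value against position on chromosome I in Mb (ce11), with thresholded regions in red, other pooled candidates in grey, and annotated genes below with let-607 in red. The 17 thresholded regions lie between 6554659 and 6589225.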

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

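The settings without the let-607 run, without regions near tRNA genes, and the 6-mers were chosen only after the data were seen. No paired analysis was possible because the series has a single group. Among tested values that answer a comparison, 301 alternatives kept their side of the threshold and did not change direction, 12 gained and 9 lost a call, and 12 changed direction, all 12 in results that had not passed; the cause was not tested. Among counts and shares with no test, 20 stayed within the counting interval or 1.5 times the main value and 4 did not. The number of lists that passed, 11, ranged from 8 with the 500 to 100 bp window to 14 with the 2000 to 500 bp window and against all protein-coding genes. Replicate overlap was 61.3% with summits within 100 bp, 71.9% for 744 regions and 56.7% for 2976. With the 744 strongest regions, N-glycosylation (3.71-fold) and ER-associated degradation (5.22) passed, collagens (0.240) no longer did, and 282 8-mers passed, with fewer tested. These regions also turned fatty acid synthesis to 0, and the proteasome and germline markers to 1.07 each. With the 500 to 100 bp window fatty acid synthesis (0.853) and the mitochondrial unfolded protein response (0) changed direction, and COPI (3.62), collagens (0.220) and chemoreceptors (0.412) did not pass. With the 2000 to 500 bp window phosphatidylcholine synthesis (3.68), heat shock (2.96) and vacuolar ATPase (4.14) passed, and the mitochondrial response was at 0.828. With the nearest start alone, phosphatidylcholine synthesis passed (5.09), ER-Golgi tethering did not (2.44), ER targeting fell to 7 of 13 and ribosomal genes to 16 of 70 bound, and fatty acid synthesis (0.969) and the mitochondrial response (0) changed direction. Against all protein-coding genes N-glycosylation (4.17), heat shock (5.21) and vacuolar ATPase (3.97) passed, and the proteasome rose above 1 (1.26). Against GC-matched candidates TGACGTGG (1.65) did not pass, and WWTRTCAT (1.84) changed direction and passed. Leaving out each replicate gave 3.10 to 4.03 for ER-associated degradation, 3.76 to 4.40 for heat shock, 0.278 to 0.427 for collagens, 3.54 to 5.76 for vitellogenins, 0.768 to 1.57 for fatty acid synthesis, 0.621 to 1.27 for germline markers, 1.01 to 2.07 for the mitochondrial response, 0.384 to 0.787 for histones, 0.931 to 0.954 for the proteasome, 2.69 to 4.13 for phosphatidylcholine synthesis, 3.00 to 6.75 for TGACGTGG and 2.08 to 4.38 for GAGAGAGA. Of 58 bound named genes, 55 stayed bound without the let-607 run, 48 with the narrow window and 45 with the nearest start alone. The 3 genes lost without the run had their regions in it, so their loss was fixed in advance. Read depth is unknown, so regions below the threshold are not shown to be unbound.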

Other observations

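The gene-name families, the 6-mers, the signal octiles, the run coverage, the counts near tRNA genes, the clustering of regions and the elements ACGTG and CCACG were chosen only after the data were seen. The bounds for the promoter share of the run, the shared promoters, the ACGTG comparisons, the CCACG comparison and the share near tRNA genes below the threshold were written before those results.

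Of 189 gene-name families, 5 passed. Besides sec (10 of 13, Fisher's exact adjusted p = 2.97e-05), rpl (15 of 39, exact adjusted p = 0.00186) and rps (11 of 28, exact adjusted p = 0.0131), which overlap the fixed lists, these were eef and lin. All 6 eef genes with a candidate region, which encode translation elongation factors, were bound (eef-1A.1, eef-1A.2, eef-1B.1, eef-1B.2, eef-1G and eef-2; Fisher's exact adjusted p = 0.000328), though eef-1A.1 and eef-1A.2 are near-identical copies. Of 31 lin genes, 11 were bound (exact adjusted p = 0.0291): lin-9, lin-13, lin-28, lin-35, lin-36, lin-46, lin-49, lin-52, lin-53, lin-54 and lin-59. The lin name marks a mutant phenotype, not a pathway; lin-9, lin-35, lin-52, lin-53 and lin-54 encode members of the DREAM repressor complex, which was not tested as a group. The vit (4 of 6) and pqn (9 of 26) families missed the threshold, each with an exact adjusted p of 0.0759.

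Regions differed along the signal ranking. In 8 bins of 186 regions, ACGTG was at 39.8% of summits in the strongest bin, 30.6% in the next and at most 24.7% in the other 6, and a secretory gene was in the window of 18.8% in the strongest bin and 1.61% in the weakest. ACGTG was at 38 of 68 regions with a secretory gene in the window (55.9%) and at 322 of 1420 others (22.7%, Fisher's exact p = 1.31e-08). Among 6-mers in the 744 strongest regions, ACGTGG led, in 124 summit windows against a flank mean of 20.5 (exact adjusted p = 1.08e-17), followed by CGTGGC in 105 against 13.5. One hypothesis was that a CCACG element serves secretory regions without ACGT. Of 19 such regions, 4 had CCACG at the summit and 3 in the left flank, which left it open with so few regions (exact McNemar p = 1).

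The 17 regions around let-607 formed the run with the most regions in the genome, counting regions less than 10000 bp apart. The next runs held 7 regions each, but the run was singled out for its size and this bound was set after it was seen, so ordinary clustering of binding sites stays open. Some of the 17 regions ranked far apart in the replicates, so the size of the run rests partly on regions that differ between them. The region at 6585405 ranked 207 in replicate 1 and 7432 in replicate 2, and the xpg-1 region 2430 and 626. The strongest let-607 region ranked 49 and 71. Candidate regions covered 46.1% of the run, 9.06% of the same length to its left and 5.87% to its right, and none of 20001 overlapping windows elsewhere passed 39.1%. Extra copies of the fosmid transgene may be a source of the run. They predicted fewer summits in promoter windows, and 5 of 17 lay there (29.4%) against 790 of 1471 others (53.7%), but Fisher's exact p = 0.0524 lies just above 0.05, the bound written beforehand, by less than the counting error. The strongest candidate over unc-119, the marker of the same transgene, ranked only 2982 in the pooled list (signal 81.3), which gives extra copies no support there, though the labels do not say which unc-119 sequence the transgene holds. So the explanation cannot be told apart from real sites and stays open.

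Regions at ribosomal protein genes were weighed next. Promoters shared with secretory genes are argued against, since 3 of the 26 bound ribosomal genes shared a region with one. The same ACGT-type element as at secretory genes is argued against too: ACGTG was at 2 of 23 regions (8.70%), against 37 of 65 at secretory genes alone (56.9%, Fisher's exact p = 5.39e-05). Whether these promoters draw signal in unrelated ChIP experiments was not analysed here and stays open. The same limit holds for the regions at secretory genes, tRNA genes and all other genes named here.

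A tRNA gene lay within 500 bp of 143 thresholded summits (9.61%), against 1.36% of other candidates (Fisher's exact p = 7.76e-65), and 164 of 612 tRNA genes had such a summit. ACGTG was at 9.79% of these summits and 25.7% of the others (exact p = 7.67e-06), which argues against recognition of that element. The regions were fewer among the stronger 744 (39) than among the weaker 744, which raised low-specificity signal near the detection limit as an explanation. The prediction written for it was that the share goes on rising below the threshold. Of the next 744 candidates 73 (9.81%) were near a tRNA gene, fewer than of the weaker 744 (exact p = 0.0161), so it was not met. Low-specificity signal need not give a share that keeps rising down the list, so this test cannot decide on that explanation. What draws these regions stays open. Without them the share on X was 21.1% with an odds ratio of 1.16 (exact p = 0.0294), against 1.40 with them.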
